A study of Spongilla lacustris with 5 samples.

How the data were processed

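The series profiled dissociated whole-body cells of juvenile Spongilla lacustris, 8 days old and grown from gemmules at room temperature. Per the labels, 4 samples were captured in 10x droplets with version 2 of the 3' kit. Samples 1 to 3 were sequenced in 2 runs and sample 4 in 1 run. A bulk RNA library of the series was not analysed here. Per the submitters' processing notes, Cell Ranger 2.1.1 was used. The reference to which reads were assigned is not given in the sources used here, and no genome was used. The authors deposited 1 matrix of raw UMI counts per gene ID and cell for all single-cell samples, with no normalization. Its barcodes carried suffixes 1 to 4, which were taken as 4 libraries and are called libraries or replicates 1 to 4. No label tied a suffix to a given sample, so the sequencing runs could not be set against the libraries. Nothing said that the samples came from separate sponges or cultures, so p-values measure only the spread between these libraries, which may be technical.

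Of 26157 gene IDs, 9379 carried an annotation in the deposited names and 7745 of these a gene symbol of another animal. The named orthology was 1-to-1 for 3235 IDs, 3477 names came from an eggNOG mapping and 313 from a BLAST match. IDs without annotation held 27.2% of UMIs. Symbols such as RAC2/RAC3 mark an ID related to several genes, and several IDs can share a symbol. The deposited description of an ID can differ from its symbol, and 3 such IDs are not named in the results. Values of IDs with a shared symbol are uncertain, since reads of near-identical copies could be split between them. Nothing marks what RNA was free in the droplets, and no correction for it was made.

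All 10106 cells had at least 200 genes. Doublets were called per library with scrublet in scanpy 1.11.5, which marked 32 cells or 0.317%, a low share for this many cells. Whether the caller missed doublets or they had been removed before deposit was not tested. The 32 were removed, which left 10074, and doublets may remain in any cluster. Gene IDs were divided before clustering, with 12669 for clustering and 13488 held out for tests. All 141 markers were on the clustering side, all 1045 members of the gene lists were held out, and other IDs were assigned at random by gene name and assembly component. Cells were scaled to 10000 counts, log-transformed and clustered on 2000 variable genes, 40 principal components, 15 neighbours and Leiden resolution 1.0 with seed 1 (leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Markers, lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule that turns markers into a cluster name was set after. It asked for at least 3 markers and 33.3% of those detected to be at least 2-fold higher than in all other cells, a median above 0, and no other type's markers in the majority among the 10 leading genes. No marker of sclerocytes and no gene of the algal symbiont list matched an ID. The planned comparison of choanocyte-like with pinacocyte-like cells was not made, since no cluster took the latter name. Of 28 classes, 21 had at least 10 cells in 3 or more libraries and were tested.

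For each class the counts were summed per library over its cells and over all other kept cells, and these 2 sums were compared with edgeR 4.0.16 (TMM factors, glmQLFit and glmQLFTest, library as a block) in R 4.3.3. The block follows from the construction, as both sums come from the same library. Genes with at least 10 UMIs in at least 3 sums were tested. The sums of all other cells could pass this filter alone, so genes near 0 in a small class were tested as well. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Comparisons share cells and are not independent of each other. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01). For the 21 classes p was adjusted over 483 pairs of a list and a class. For each other comparison it was adjusted over its 23 lists alone. Lists needed at least 5 tested genes. Camera compares the members of a list with the other tested genes, so a list called higher or lower is so relative to them. Its members need not have risen or fallen. The estimated correlation of camera and fry were alternatives. With 2 sums in each of 3 or 4 libraries, the estimated correlation and its test rest on few residual degrees of freedom. After adjustment that setting could hardly call a list, so its lack of calls does not decide whether a list differs. The calls given here rest on the preset correlation. Named genes were, per class, up to 4 members per called list with the largest absolute fold change, and the 10 highest and 5 lowest called genes with a log2 CPM of at least 5. All had to move the same way in every library, with at most 30 per class, which gave 657 gene and class pairs. The rule gave no order in which lists fill these places, and alphabetical order ignoring case was used. With capitals first, other genes would have been named in part. Genes outside this rule are said to be chosen after their values were seen. The markers printed with their folds also lie outside it, and were picked from the preset marker lists after their values were seen. The results of 3 genes are not reported here.

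The procedure was tested on simulated counts. For the choanocyte-like comparison (7389 genes), 95 of 99 genes changed 4-fold and 39 of 99 changed 2-fold were called, with 1 of 7161 unchanged genes called. For cluster 25 (7415 genes), the numbers were 48 of 100, 18 of 97 and 2 of 7188. For choanocyte-like against archaeocyte-like cells (5919 genes), they were 93 of 93, 44 of 96 and 0 of 5700, with 11 of these at an adjusted p under 0.05. A simulated list of 30 genes moved 1.5-fold was called in each, and 0 of 20 random lists were. Genes were simulated independently of each other, so this cannot show how often lists of correlated genes are called falsely. Outside the list, only 198 of the 7389 genes were changed for the choanocyte-like comparison, about as many up as down. In the data 43.5% of its tested genes were called. How often scaling leads to false calls when so many genes differ is therefore not shown either.

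Alternatives were DESeq2 1.42.0, its size factors or none in edgeR, no count filter or 50 UMIs, no block, no minimum fold, other clusterings and leaving out each library. For a class tested in 3 libraries, leaving 1 out left too few sums of other cells to pass the filter alone. Fewer genes were then tested, for cluster 19 1679 in place of 7585 without library 1. Such counts and list tests therefore do not show the effect of that library alone. Without scaling factors the median log2 fold change of all genes shifted by -1.01 to 0.11 between classes, and with DESeq2's size factors by -0.31 to 0.17, so fold changes are relative to the TMM centre. Added after seeing the data were the comparison within the choanocyte-like class, those of cluster 5, and leaving out libraries 2 and 4 together. The R package data.table had version 1.17.8, and plots were drawn with matplotlib 3.10.9.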

Results

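Gene expression was measured in single cells of the freshwater sponge Spongilla lacustris, an animal with no neurons or muscle, at 8 days after juveniles began to grow from gemmules, the dormant buds from which this sponge regrows. The 4 droplet libraries formed 1 group of dissociated whole juveniles, so every comparison was made between classes of cells within libraries. The deposited matrix held 26157 gene IDs and 10106 cells with 137481454 unique molecular identifiers (UMIs, 1 per captured RNA molecule). Libraries 1 to 4 held 5046, 2298, 2464 and 298 cells with 70922297, 29133713, 34979657 and 2445787 UMIs. Median UMIs per cell were 10647, 9519.5, 10271 and 3820, and median genes per cell were 3052, 2548.5, 2956 and 1535, so that library 4 was the smallest and shallowest. Across genes, log2 CPM of the libraries correlated with Pearson r between 0.965 and 0.990, where genes are not independent replicates. The study asked which cell types a sponge holds and how they relate to those of other animals.

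The 10074 kept cells fell into 31 clusters, of which 5 carried the name of a known sponge cell type. Choanocyte-like cells, named for the flagellated cells that drive water through the sponge and catch food, were clusters 7, 8, 11 and 15. Of 75 detected markers of cilia and flagella, 56, 57, 37 and 40 were at least 2-fold higher there than in all other cells. These cells made up 19.6% ± 7.58 (SD, n = 4 libraries) of all cells, with 14.5%, 18.6%, 14.7% and 30.6% in libraries 1 to 4. Cluster 11 held 68 of the 89 choanocyte-like cells of library 4, while clusters 7 and 8 held most of them in the other 3 libraries. Archaeocyte-like cells, named for the wandering stem cells of sponges, were cluster 1 alone, which met the rule at its limit with 4 of 12 markers. DDX4 at a log2 fold of 1.30 and a PIWIL1/PIWIL4 ID at 1.24, both from the germ line and stem cell machinery, were among the 4, while MSI1/MSI2 at -2.23 and NANOS1 at -1.95 were lower in that cluster. This class took 13.1% ± 11.3 of cells (n = 4), ranging from 1.62% in library 2 to 23.02% in library 3. Cluster 5 ran the other way, with 23.98% in library 2 and 1.07%, 2.16% and 5.84% in libraries 1, 3 and 4.

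No cluster met the rule for pinacocytes, the flat cells that line the body, or for lophocytes, which move through the body and lay down collagen. Clusters 2, 9, 12, 19, 27 and 28 each had 2 of 6 pinacocyte markers at least 2-fold higher, below the minimum of 3. These were the calponin CNN3 (c79401_g1) at log2 folds of 2.24, 2.49, 3.21, 3.88, 3.53 and 2.40 and the tropomyosin TPM1 (c105153_g1) at 1.29, 1.66, 1.79, 3.15, 2.79 and 1.59, both proteins of contractile actin filaments, while another CNN3 ID (c79207_g1) was lower in all 6. The first 5 took 9.30% ± 1.5, 4.67% ± 0.887, 4.05% ± 3.03, 1.34% ± 0.297 and 0.430% ± 0.217 of cells (n = 4), where the third, cluster 12, took 2.53% without library 4. The threshold of 33.3% of markers, which was set after the values had been seen, kept out clusters 3, 24 and 28, with 18, 18 and 21 of 75 choanocyte markers and 6.74% ± 3.06, 0.430% ± 0.322 and 0.385% ± 0.217 of cells. It also kept the lophocyte name from clusters 22 and 30, with 3 and 5 of 18 of its markers and 0.903% ± 0.339 and 0.161% ± 0.168 of cells. Cluster 1 had 4 of 18 lophocyte markers, at a median log2 fold of 0.17 against 0.41 for archaeocyte markers. A cluster took the type with the highest median, so cluster 1 would have kept its name without the threshold. Clusters 4, 6 and 10 took 7.25% ± 0.983, 6.64% ± 2.01 and 3.00% ± 0.860. Clustering had used the library-specific differences as they were, and no gene tested for differences had been used in it.

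**Figure D1:**
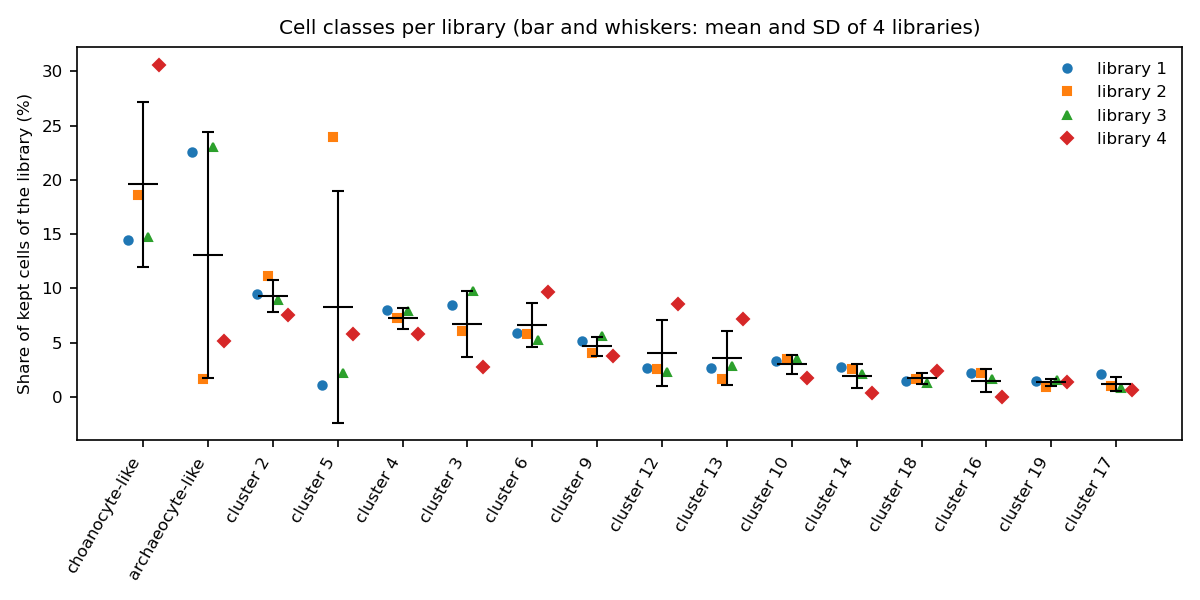
Share of each cell class among the kept cells of a library, in percent, for classes with a mean share of at least 1%. Points are the 4 libraries and black bars with whiskers their mean and SD. The archaeocyte-like class is low in libraries 2 and 4, where cluster 5 is higher than in libraries 1 and 3.

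Choanocyte-like cells differed from all other cells at 3307 of 7602 tested genes, with 1345 higher and 1962 lower in the edgeR quasi-likelihood test. Values below are log2 fold changes ± SD over libraries (n = 4 unless given as n = 3), each the same way in every library and called at a Benjamini-Hochberg adjusted p of 0.0489 or less. Genes of the apical microvilli, the actin-cored protrusions that form a collar around the flagellum in choanocytes, were higher for 10 of 20 list members and lower for 1. They included the actin bundler ESPNL/ESPN at 4.92 ± 0.46, the scaffold ANKS4B/USH1G at 4.63 ± 0.72 and EPS8L2 at 3.82 ± 0.64. Of the postsynaptic scaffold list, whose proteins organise receptors under synaptic membranes in other animals, 9 of 19 members were higher and 1 lower, with a DLG1/DLG3 ID (c103212_g4) at 4.30 ± 1.37, DLG2/DLG4 at 4.04 ± 0.24 and HOMER2/HOMER1 at 2.68 ± 0.25. Of 32 cell cycle genes 23 were higher and 2 lower, with CCNA1/CCNA2 at 3.21 ± 0.27, CCNB1/CCNB2 at 1.77 ± 0.44 and the spindle motor KIF11 at 1.81 ± 0.31. Outside the lists called in this class, the flagellar proteins NME5 and RIBC1/RIBC2 were higher at 4.53 ± 0.26 and 4.40 ± 0.55. So were the adhesion receptor CELSR3 at 4.51 ± 0.30 and the dystrophin DMD at 4.46 ± 0.37. CELSR3 belongs to the junctions and polarity list, which was not called here. Lower lists were ribosome biogenesis (37 of 43 members lower, 1 higher), ribosomal proteins (59 of 108, 1 higher), endoplasmic reticulum secretion (12 of 42) and the TGF-beta and BMP pathway (9 of 17, 1 higher). Examples were NOP58 at -3.86 ± 0.36, NHP2 at -3.89 ± 0.41, RPL23A (c40200_g1) at -2.25 ± 0.29, SEC63 at -2.58 ± 0.43 and SPCS3 at -1.41 ± 0.23. These 7 lists had adjusted p values between 3.93e-09 and 0.0102 in limma's camera test with a preset correlation, and between 0.819 and 0.833 with an estimated correlation. Here and below, counts adjusted over the list alone were equal to those over all genes tested except where a second count is given.

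**Figure D2:**
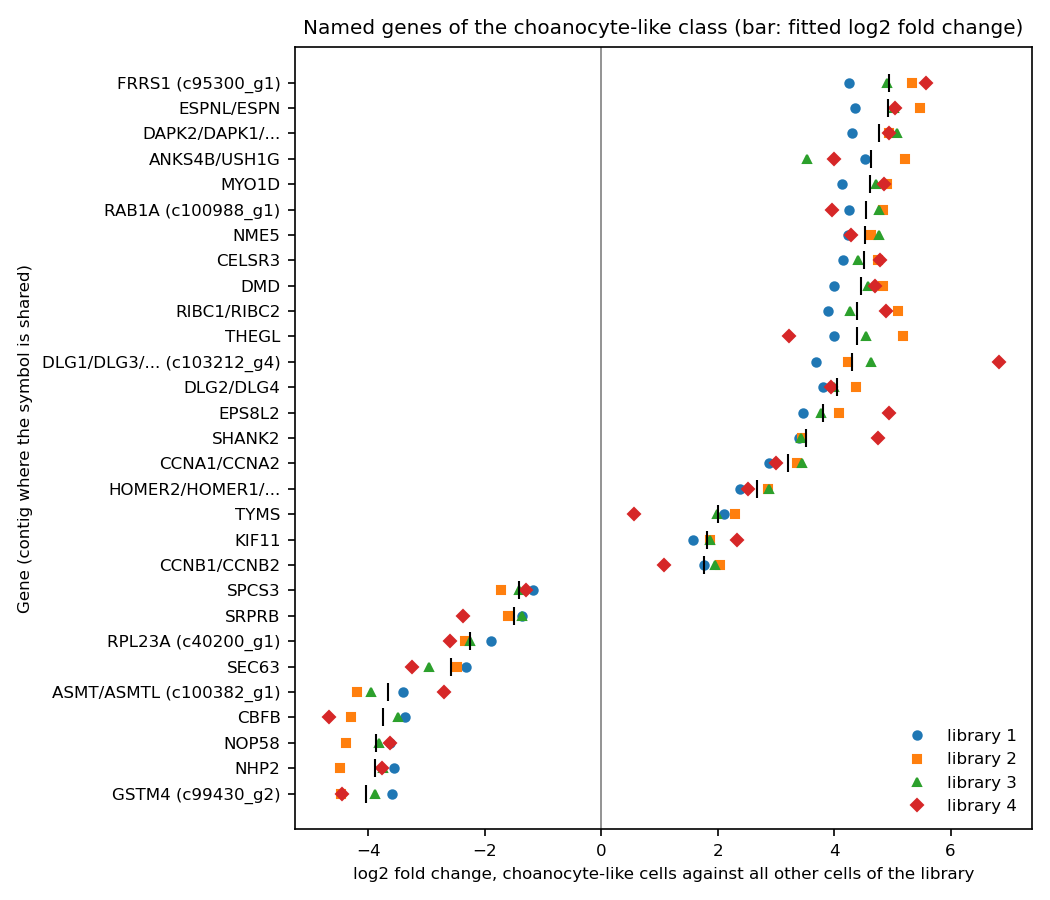
Log2 fold change of genes picked by the rule for named genes, choanocyte-like cells against all other cells of the library, for genes with at least 10 CPM in both sums added. Points are the 4 libraries and black bars the fitted value. Each gene lies on the same side of 0 in every library.

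Within the choanocyte-like class, clusters 11 and 15 were set against clusters 7 and 8, a comparison added after the clusters had been seen. Cells of clusters 11 and 15 had lower levels of 27 of 28 cell cycle genes, among them the DNA clamp PCNA at -4.07 ± 0.24 (79.2 against 1331 CPM), the replication helicase subunits MCM4 at -3.94 ± 0.73 and MCM3 at -3.88 ± 0.67, and CCNE1/CCNE2 at -3.55 ± 0.49. Ribosomal proteins were lower for 61 of 104 IDs (1 higher), oxidative phosphorylation for 17 of 45 and endoplasmic reticulum secretion for 24 of 39, with the disulfide isomerases PDIA3 at -2.87 ± 0.41 and PDIA6 (c87990_g1) at -2.62 ± 0.43. Another member of that list, SSRP1 at -3.12 ± 0.51, is a histone chaperone that matched it by its symbol. Higher lists were actin motility (9 of 31 members higher, 1 lower), presynaptic release (16 of 50 higher, 3 lower) and actomyosin and adhesion (9 of 33 higher). Their members included a RAC2/RAC3 ID (c102226_g1) at 2.05 ± 0.34 and WASL, which starts branched actin, at 1.62 ± 0.85. The signal protein WNT9A at 5.66 ± 1.71, the transcription factor FOXL2 at 4.60 ± 1.08 and the phosphatase DUSP28 at 5.88 ± 0.96 were also higher. The adjusted p of these 7 lists lay between 4.37e-10 and 0.00103, and between 0.218 and 0.307 with an estimated correlation. The lysosome and digestion list was called higher as well (adjusted p = 0.0332, and 0.613 with an estimated correlation) but lost the call without replicate 1, 2 or 3, at 0.276, 0.0748 and 0.207. Its named members CTSH, GLB1L3/GLB1L2 and SCARB2 were lower, at -2.18 ± 0.45, -2.03 ± 0.80 and -1.60 ± 0.35. In all, 786 of 4847 genes were higher and 1216 lower, 2002 together, and 1309 without replicate 1.

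Archaeocyte-like cells had higher levels of the machinery that builds ribosomes than all other cells, with 40 of 43 ribosome biogenesis genes higher and 1 lower. NOLC1 at 2.34 ± 0.71, NOP58 at 2.28 ± 0.72, WDR12 at 2.27 ± 0.60 and NOP56 at 2.16 ± 0.73 led that list, and the methyltransferase FBL stood at 2.24 ± 0.92. Ribosomal proteins were higher for 58 of 108 IDs, oxidative phosphorylation for 4 of 47 and endoplasmic reticulum secretion for 6 of 43, with 1 lower. The mitochondrial chaperone HSPD1 was at 2.37 ± 0.88. Lists that were lower were actomyosin and adhesion (17 of 41 members lower), presynaptic release (18 of 60 lower, 2 higher), postsynaptic scaffold (11 of 20), actin motility (7 of 37) and microvillus (8 of 20). Also lower were the Notch pathway (9 of 20), channels and receptors (15 of 31) and non-collagen matrix and integrins (11 of 23 lower, 1 higher). A RAC2/RAC3 ID (c102226_g1) fell by 2.21 ± 0.88 and PI16 by 3.24 ± 0.97. The 12 lists had adjusted p between 7.81e-13 and 0.0485, and between 0.819 and 0.833 with an estimated correlation; channels and receptors lost its call without replicate 1, 3 or 4, at 0.108, 0.0717 and 0.0664, and the matrix list with DESeq2's size factors or none, at 0.0612 and 0.0697. In all, 1159 of 8045 genes were higher and 1685 lower, and without scaling factors 715 were higher and 2087 lower.

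In cluster 5, set against all other cells, 27 of 42 ribosome biogenesis genes were higher (28 adjusted over the list alone) and 1 lower, and 10 of 108 ribosomal proteins were higher (11 alone) and 1 lower. TRMT112, a partner of RNA methyltransferases, was at 1.64 ± 0.76, TIMM8A, a mitochondrial import chaperone, at 1.52 ± 0.58 and the nucleolar protein SURF6 at 1.47 ± 0.61. Oxidative phosphorylation and endoplasmic reticulum secretion were called higher with no member higher past the gene threshold and 1 lower in the latter (0 alone). Actomyosin and adhesion was lower for 21 of 37 members (23 alone), channels and receptors for 17 of 29, postsynaptic scaffold for 12 of 19 (13 alone) and non-collagen matrix and integrins for 10 of 22, with 1 higher. The stress response list was called higher, with 2 of 13 members higher and 3 lower, and was not called without replicate 1, 3 or 4, at 0.0672, 0.117 and 0.125. Without replicates 2 and 4 together, the oxidative phosphorylation and endoplasmic reticulum lists were not called either, at 0.2996 and 0.492. These 9 lists had adjusted p between 1.86e-18 and 0.0382, and between 0.819 and 0.833 with an estimated correlation. The count of 541 higher and 1659 lower of 7377 genes, 2200 in all, was 852 without replicate 2 and 220 without replicates 2 and 4. Set directly against the archaeocyte-like class, cluster 5 differed at 1 of 5921 genes in edgeR, an ID with no name (c64214_g1) at 1.79 with an adjusted p of 0.0275, named here after its value had been seen. At an unadjusted p under 0.05 there were 439 genes, DESeq2 called 0, and without scaling factors 2 were higher and 1 lower. Ribosomal proteins were the 1 list called higher in cluster 5 there (adjusted p = 9.38e-07, and 0.928 with an estimated correlation), with 0 of 107 members called. When both were joined, a step added after the shares had been seen, 1301 of 7980 genes were higher and 1696 lower than in all other cells (798 and 2187 without scaling factors). NOP58 was at 2.81 ± 0.45, FBL at 2.78 ± 0.40, the arginine methyltransferase PRMT1 at 2.66 ± 0.39 and the chaperone HSPD1 at 2.83 ± 0.62. The joined class had 13 lists called, with adjusted p between 0.455 and 0.528 with an estimated correlation, among them nitric oxide and cGMP, lower for 4 of 7 members at an adjusted p of 0.0313.

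Choanocyte-like cells set directly against archaeocyte-like cells, the feeding against the stem-like cells, differed at 2928 of 6148 genes, with 1485 higher and 1443 lower in choanocyte-like cells (1919 and 1148 without scaling factors). NME5 was higher at 5.48 ± 1.65, CELSR3 at 5.31 ± 1.17 and CCNA1/CCNA2 at 3.76 ± 0.37. Lower were NOP58 at -5.01 ± 0.27, NHP2 at -4.90 ± 0.16, HSPD1 at -4.68 ± 0.38, GSTM4 (c99430_g2) at -5.17 ± 0.47, SEC63 at -3.31 ± 0.47 and SRP68 at -2.01 ± 0.31. Ribosome biogenesis was lower for 35 of 38 members (1 higher), ribosomal proteins for 60 of 108 (1 higher), endoplasmic reticulum secretion for 17 of 40 and the TGF-beta and BMP pathway for 7 of 15 (1 higher). Postsynaptic scaffold was higher for 11 of 19, actomyosin and adhesion for 16 of 40, cell cycle for 17 of 31 (1 lower), actin motility for 9 of 35 (1 lower), microvillus for 10 of 19 (1 lower) and presynaptic release for 19 of 57 (4 lower). Oxidative phosphorylation, lower for 6 of 47, lost its call without replicate 4, at 0.0568, and without scaling factors, at 0.263. Actin motility lost it without replicates 2 and 4 together, at 0.0541. The 11 lists had adjusted p between 7.29e-13 and 0.0334, and between 0.578 and 0.664 with an estimated correlation.

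Among the clusters with high CNN3 and TPM1, cluster 9 had 926 genes higher and 1733 lower of 7574. Actomyosin and adhesion genes were higher for 21 of 39 and lower for 1. A TLN1/TLN2 ID (c103122_g3), a talin that ties integrins to actin, was at 6.38 ± 0.32, TLN2 at 3.29 ± 0.14 and the serum response factor SRF (c79489_g1), a regulator of cytoskeletal genes, at 2.49 ± 0.32 and 7377 CPM. Other higher lists were the Notch pathway (8 of 19 members, 2 lower), with the ligand DLL1 (c100515_g1) at 6.13 ± 0.62 and MIB2 (c102460_g4) at 3.62 ± 0.54, and junctions and polarity (9 of 16, 2 lower), with PARD3 at 2.63 ± 0.58 and SCRIB/LRRC1 at 2.35 ± 0.51. Actin motility (10 of 37), with CDC42 at 1.46 ± 0.15, presynaptic release (17 of 59, 1 lower) and postsynaptic scaffold (9 of 19, 3 lower) were higher too. Wnt pathway genes were called higher, with 2 of 11 members higher and 1 lower, and were not called without replicate 1, 2 or 3, at 0.119, 0.156 and 0.114, and junctions and polarity was not called without replicates 2 and 4 together, at 0.192. The transcription factor PAX5 was at 4.19 ± 0.11, PI16 at 5.09 ± 0.52 and TNXB (c103990_g2), a matrix protein, at 5.31 ± 0.74. Ribosomal proteins were lower for 60 of 108 members, with 2 higher, and ribosome biogenesis for 36 of 42 (37 alone). These 9 lists had adjusted p between 1.90e-10 and 0.0382, and between 0.819 and 0.859 with an estimated correlation.

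Cluster 19 (n = 3 libraries) had 725 genes higher and 1636 lower of 7585, 2361 in all, and 751, 1191 and 1159 without replicates 1, 2 and 3. The growth factor binding protein CRIM1 at 8.05 ± 0.45, TMTC1 (c79439_g1) at 7.63 ± 0.19 and the matrix protein THBS1/THBS2 at 4.67 ± 0.31 were higher, as were the small GTPase RHOV/RHOU at 4.49 ± 0.20 and PDLIM7/LDB3 at 3.21 ± 0.20. Actomyosin and adhesion was higher for 14 of 39 members (15 alone) and lower for 2, the Wnt pathway for 6 of 11, non-collagen matrix and integrins for 10 of 22, with 2 lower, and nitric oxide and cGMP for 1 of 7. The disulfide isomerases PDIA3 at -3.10 ± 0.73 and P4HB at -2.33 ± 0.41 were lower. Lists that were lower were endoplasmic reticulum secretion (23 of 42, 24 alone, with 1 higher), ribosomal proteins (60 of 108, with 1 higher), ribosome biogenesis (30 of 42, 31 alone), oxidative phosphorylation (29 of 47) and cell cycle (27 of 31). Junctions and polarity (5 of 16 higher, 6 alone, and 3 lower), postsynaptic scaffold (7 of 19, 1 lower, 2 alone), presynaptic release (5 of 60, 6 lower), transcription factors (9 of 52, 6 lower, median -0.14), actin motility (3 of 37, 1 lower) and the TGF-beta and BMP pathway (6 of 17, 3 lower) were called higher. Without replicate 1 all 6 had adjusted p between 0.0725 and 0.805. That setting tested 1679 genes in place of 7585, so the genes each list was compared with changed as well. The effect of the replicate itself cannot be told apart from this. Without replicate 2 the first 4 had 0.0842 to 0.419, and without replicate 3 all 6 had 0.0957 to 0.390. The 15 lists had adjusted p between 3.62e-08 and 0.0385, and between 0.819 and 0.917 with an estimated correlation.

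Cluster 12, with 370 of 7575 genes higher and 469 lower, had 839 calls in all, 497 without replicate 2 and 492 without replicate 3. CHD64, a calponin-domain protein, was at 14780 against 2854 CPM, a log2 fold change of 2.34 ± 0.20, and the vesicle calcium sensor SYT4/SYT11 at 2.83 ± 0.86. Actomyosin and adhesion was higher for 12 of 39 members, postsynaptic scaffold for 4 of 19 (5 alone) and presynaptic release for 6 of 60. Ribosome biogenesis was lower for 22 of 42 (24 alone). Ribosomal proteins were called lower with 1 of 108 members higher and 0 lower, the 1 being RPS6KA6/RPS6KA3, a kinase of a ribosomal protein. Cluster 2 had 362 higher and 840 lower of 7575 genes, and 264 and 1177 without scaling factors. It differed by 5 of 41 endoplasmic reticulum secretion genes, all higher, with P4HB at 1.26 ± 0.17, and a TGFB1/TGFB3 ID (c99909_g1), a secreted signal, at 3.80 ± 0.30, with SMAD9/SMAD1, which relays BMP signals, at 1.64 ± 0.25. The metalloprotease LMLN (c103727_g1) was at 5.09 ± 0.27 and the protease inhibitor TFPI2 (c100418_g1) at 4.23 ± 0.22. Called higher in cluster 2 were also the TGF-beta and BMP pathway (4 of 17, 2 lower), the Wnt pathway (4 of 11), transcription factors (8 of 52, 2 lower) and actomyosin and adhesion (6 of 40, 6 lower), and ribosome biogenesis was lower for 12 of 42. The TGF-beta and BMP list in cluster 12 (4 of 17 higher, 4 lower) was not called without replicate 1 or 2, at 0.0862 and 0.120, and oxidative phosphorylation in cluster 2 (0 of 47) not without replicate 1 or 3, at 0.0665 and 0.118. The 13 lists of both clusters had adjusted p between 3.93e-09 and 0.0341, and between 0.819 and 0.867 with an estimated correlation.

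**Figure D3:**
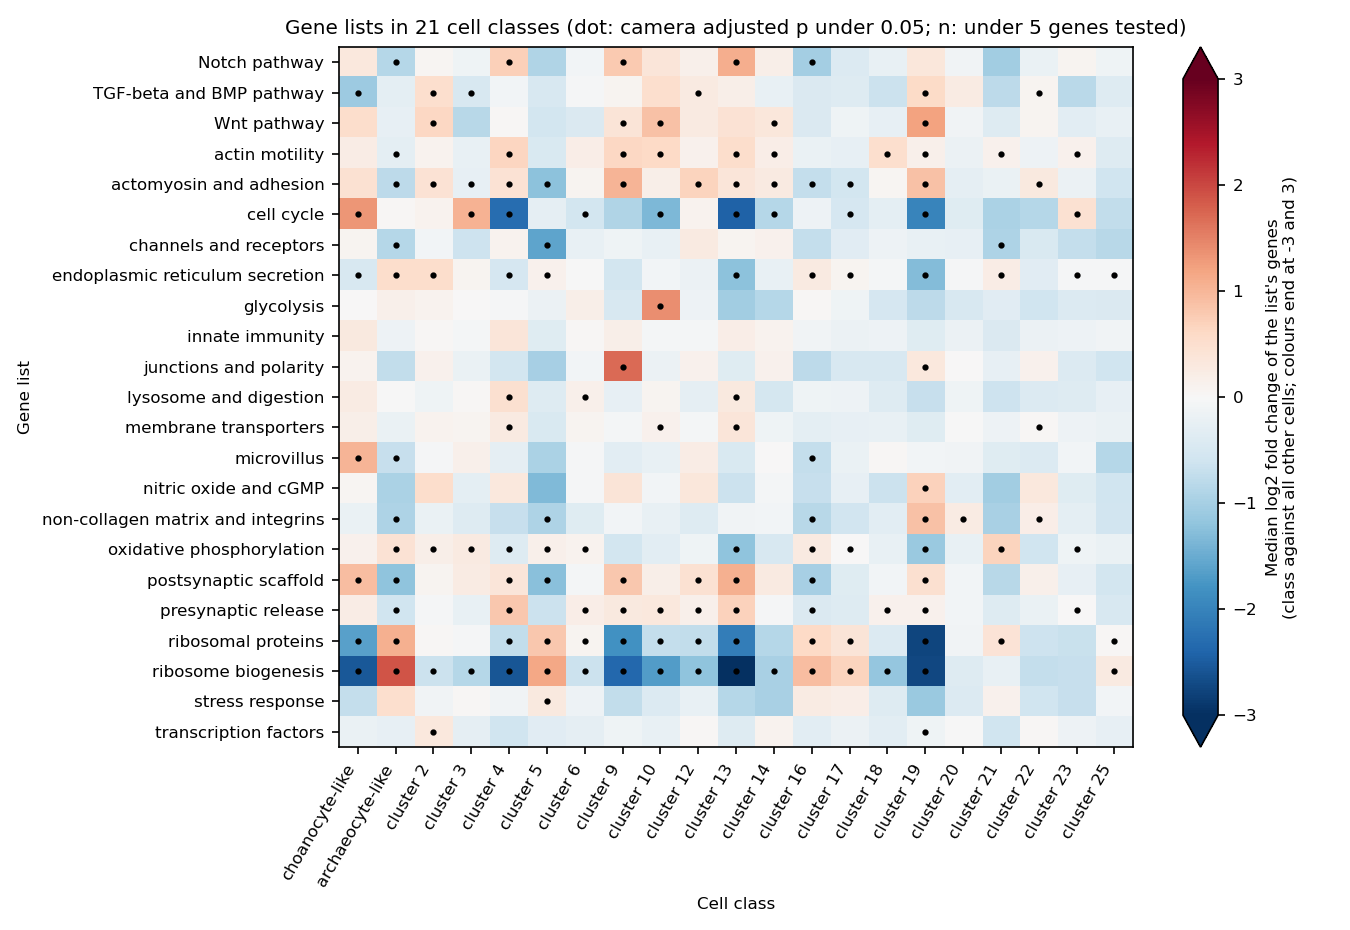
Median log2 fold change of the members of each gene list in each tested class against all other cells, as a colour scale. Marked squares are lists called by camera with the preset correlation. Ribosome biogenesis is called higher in 5 classes and lower in 12, and with an estimated correlation no list is called in any class. So few libraries could hardly give a call with an estimated correlation.

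Clusters 4, 13 and 6 were each called higher for the presynaptic release list. The copper transporter SLC31A2 was at 3.66 ± 0.36 in cluster 4 and 4.10 ± 0.34 in cluster 13, the endosomal tetraspanin CD63 (c97008_g1) at 3.62 ± 0.26 and 4.13 ± 0.59. The vesicle GTPase RAB26/RAB37 (c98770_g1) stood there at 3.52 ± 0.30 and 3.79 ± 0.55, the hydrogen peroxide producing oxidase DUOX1 (c102802_g2) at 2.79 ± 0.55 and 4.01 ± 0.40, and a RAC2/RAC3 ID (c102226_g1) at 2.43 ± 0.18 and 4.67 ± 0.21. The lysosomal thioesterase PPT2 (c100307_g1) was at 2.98 ± 0.44 in cluster 4 and 2.11 ± 0.55 in cluster 6. Presynaptic release was higher for 19 of 59, 22 of 60 and 3 of 59 members in clusters 4, 13 and 6, and lower for 7, 5 and 6. In clusters 4 and 13, actin motility (4 and 8 of 37, with 3 lower in each), lysosome and digestion (13 of 55 and 12 of 54, with 8 and 11 lower) and membrane transporters (26 of 154 and 39 of 155, with 16 and 25 lower) were called higher. So were the Notch pathway (4 and 10 of 19, with 3 and 2 lower) and actomyosin and adhesion (7 of 40 and 11 of 39, with 5 and 3 lower). Cell cycle genes were lower for 26 of 31 in cluster 4, 26 of 31 in cluster 13 (27 alone, with 1 higher) and 2 of 31 in cluster 6, with PCNA at -2.79 ± 0.46 in cluster 4 and CCNA1/CCNA2 at -1.57 ± 0.21 in cluster 6. Ribosome biogenesis was lower for 34, 38 and 9 of 42. Ribosomal proteins (48 and 60 of 108 lower, 0 and 2 higher), oxidative phosphorylation (6 and 28 of 47 lower) and endoplasmic reticulum secretion (8 of 41 and 24 of 42 lower, with 1 higher over the list alone in cluster 13) were lower in clusters 4 and 13. In cluster 6 oxidative phosphorylation and ribosomal proteins were called higher with no member past the gene threshold, the latter not without replicate 1 at 0.0570, and so was lysosome and digestion (7 of 54, 4 lower), not called without replicate 1, 2 or 3, at 0.149, 0.183 and 0.229. Postsynaptic scaffold was called higher in cluster 4 (4 of 19, 2 lower), though not without replicate 1, 2, 3 or 4, at 0.0666, 0.0905, 0.0839 and 0.0749, and in cluster 13 (10 of 19, 1 lower), though not without replicate 1 or 3, at 0.0596 and 0.0788. Without replicates 2 and 4 together, oxidative phosphorylation in cluster 6 and lysosome and digestion in cluster 13 were not called, at 0.121 and 0.147. In all, cluster 4 had 974 higher and 2013 lower genes of 7573, cluster 13 had 1232 and 2088 of 7587 (927 and 2603 with DESeq2's size factors), and cluster 6 had 228 and 841 of 7576. The 30 lists had adjusted p between 1.59e-07 and 0.0355, and between 0.819 and 0.917 with an estimated correlation.

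Cluster 10 (n = 3) had high levels of several enzymes of sugar metabolism. GPI, which interconverts glucose and fructose phosphates, was at 5.12 ± 0.18, a PFKFB4/PFKFB2 ID (c101950_g1) at 4.50 ± 0.09 and TPI1 at 2.20 ± 0.20. A receptor tyrosine kinase ID named FLT3/PDGFRA (c104180_g1) was at 8.28 ± 0.39, the protease ADAM28 at 7.90 ± 0.48, a superoxide-producing NOX3/NOX1 ID (c104085_g1) at 6.42 ± 0.52, a thiamine transporter SLC19A2/SLC19A3 (c92316_g1) at 5.65 ± 0.31 and the vesicle fusion protein STX1A (c95522_g1) at 4.31 ± 0.26. Actin motility was higher for 4 of 37 members (1 lower), presynaptic release for 12 of 60 (3 lower) and the Wnt pathway for 5 of 11 (2 lower). Ribosome biogenesis was lower for 29 of 42, ribosomal proteins for 46 of 108 (1 higher) and cell cycle for 22 of 31 (1 higher). Glycolysis was higher for 6 of 11 members and 0 were lower, and the list was not called without replicate 1, 2 or 3, at 0.130, 0.103 and 0.0558. Membrane transporters, higher for 26 of 155 and lower for 14, were not called without replicate 1, at 0.0624. In all, 722 of 7560 genes were higher and 1337 lower, 2059 together (514 and 1757 without scaling factors), and 1181 and 1362 without replicates 1 and 2. The 8 lists had adjusted p between 1.84e-05 and 0.00926, and between 0.819 and 0.891 with an estimated correlation.

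In cluster 3 (n = 3) the cell cycle list was higher. Of its 31 cell cycle genes 16 were higher and 1 lower, with MCM3 at 1.71 ± 0.24, MCM4 at 1.64 ± 0.21, MCM5 at 1.52 ± 0.06 and the ribonucleotide reductase RRM1 at 1.68 ± 0.14, and the centrosome protein PCM1 stood at 1.84 ± 0.06. Oxidative phosphorylation was higher with 1 of 47 members past the gene threshold, NDUFA10 at 1.21 ± 0.13. Ribosome biogenesis (16 of 42 lower, 1 higher), actomyosin and adhesion (9 of 40) and the TGF-beta and BMP pathway (4 of 17) were lower, with NHP2 at -2.20 ± 0.41. The higher member of ribosome biogenesis, NOL4/NOL4L at 2.91 ± 0.36, matched by its symbol. The 5 lists had adjusted p between 1.62e-10 and 0.0231, and 0.819 with an estimated correlation. Of 7589 genes 411 were higher and 1264 lower, 1675 together, and 945, 1088 and 1086 without replicates 1, 2 and 3. Cluster 23 (n = 3) also had a higher cell cycle list, with 8 of 31 members higher and RRM2B/RRM2 at 1.34 ± 0.35, and a higher presynaptic release list, with 6 of 60 higher, 1 lower and DOC2B (c62161_g1), a calcium sensor of vesicle fusion, at 2.20 ± 0.43. Actin motility was called there with 0 of 37 members past the gene threshold. Endoplasmic reticulum secretion and oxidative phosphorylation, with 1 member higher each, were not called without replicate 1, 2 or 3, at 0.220 to 0.959, and their medians of -0.02 and -0.13 ran against the test's direction. Those 5 lists had adjusted p between 1.10e-09 and 0.0192, and between 0.819 and 0.879 with an estimated correlation. Cluster 23 had 151 higher and 156 lower of 7587 genes, 307 together, against 185 and 117 with DESeq2's size factors, 185 and 114 without factors, and 146, 83 and 130 without replicates 1, 2 and 3.

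The other 8 clusters were tested in n = 3 libraries each. In cluster 14 the ETS factor ELF5/ELF3 (c82638_g1) was at 6.82 ± 0.08, the vitamin C synthesis enzyme GULO (c100503_g1) at 5.24 ± 0.91, the transcription factor FOXP2 at 4.20 ± 0.76 and CD63 (c87510_g1) at 3.95 ± 0.26. Ribosome biogenesis was lower for 16 of 42 members (18 alone), with 1 higher, and cell cycle for 7 of 31 (8 alone). Actin motility (1 of 37 higher), actomyosin and adhesion (3 of 39 higher, 1 lower) and the Wnt pathway (0 of 11) lost their calls without replicate 3, at 0.114 to 0.147. The first pair lost them without replicate 1, at 0.177 and 0.373, and actin motility without replicate 2, at 0.288. Cluster 14 had 402 higher and 558 lower of 7578 genes, 960 together, against 156 and 3231 without scaling factors. Without replicates 1 and 3, where 1805 and 3595 genes were tested, it had 116 and 355 in all. In cluster 18 NPC2 (c105271_g1), described in the deposit as a phospholipid transfer protein, was at 2846 against 8.32 CPM, 8.36 ± 0.66 on the log2 scale, the homeobox factor NKX6-3 (c97350_g3) at 2.40 ± 0.26 and a CYCS ID (c104863_g2) at 3.29 ± 0.29. Presynaptic release was higher there for 6 of 59 members and lower for 1, with DOC2B (c62161_g1) at 2.52 ± 0.11 and CADPS/CADPS2, which primes secretory vesicles, at 1.86 ± 0.52. Actin motility was higher for 3 of 37 and lower for 2, and ribosome biogenesis was lower for 19 of 42 (21 alone). Cluster 18 had 268 higher and 496 lower of 7578 genes (320 and 384 with DESeq2's size factors), 764 together, and 410, 462 and 358 without replicates 1, 2 and 3. The 8 lists of both clusters had adjusted p between 3.10e-05 and 0.0450, and between 0.819 and 0.879 with an estimated correlation.

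In cluster 21 a subunit of the proton pump that acidifies lysosomes, ATP6V0C (c100302_g1), was at 8.87 ± 0.74, the cysteine protease CTSL2 at 8.35 ± 0.49 and PRSS12 (c101205_g1) at 9.27 ± 0.79. Oxidative phosphorylation was higher for 3 of 47 members and lower for 1, with UQCRB at 1.64 ± 0.22 and NDUFA10 at -3.94 ± 0.03. Ribosomal proteins (0 of 108) lost their call without replicate 1, at 0.0539. So did endoplasmic reticulum secretion (4 of 42 higher, 1 lower alone) and actin motility (2 of 37 higher, 5 lower) without replicate 1, 2 or 3, at 0.158 to 0.575, and channels and receptors (4 of 30 lower, 3 alone) without replicate 2 or 3, at 0.357 and 0.229. Cluster 21 had 393 higher and 937 lower of 7589 genes, 1330 together (271 and 1502 without scaling factors), and 363, 790 and 715 without replicates 1, 2 and 3. In cluster 22 the TGF-beta family ligand GDF9 was at 7.55 ± 0.41, FOXL2 at 4.96 ± 0.43 and integrin IDs named ITGB4/ITGB8 and ITGAV/ITGA2B at 5.97 ± 0.63 and 4.77 ± 0.60. The TGF-beta and BMP pathway (6 of 18 higher), actomyosin and adhesion (3 of 39), membrane transporters (14 of 155, 3 lower) and non-collagen matrix and integrins (3 of 22, 4 alone) all lost their calls without replicate 1, at 0.114 to 0.468. Membrane transporters and the matrix list lost them without replicate 2 also, at 0.0679 and 0.114, and those with the TGF-beta list without replicate 3, at 0.258 to 0.429. Cluster 22 had 364 higher and 207 lower of 7591 genes, 571 together, and 238 and 235 without replicates 1 and 3. The 9 lists of clusters 21 and 22 had adjusted p between 2.72e-14 and 0.0450, and between 0.819 and 0.859 with an estimated correlation.

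In cluster 16 the receptor phosphatase PTPRD (c104563_g1) was at 3.14 ± 0.08 and FBL at 1.2 ± 0.08, 13 of 42 ribosome biogenesis genes were higher and ribosomal proteins were called higher with 0 of 108 members past the gene threshold. Actomyosin and adhesion (14 of 39), presynaptic release (15 of 60), postsynaptic scaffold (9 of 19) and microvillus (7 of 19) were lower. Endoplasmic reticulum secretion and oxidative phosphorylation (0 members each), non-collagen matrix and integrins and the Notch pathway (9 of 22 and 9 of 19 lower) lost their calls without replicate 1, at 0.0642 to 0.271. Cluster 16 had 266 higher and 1105 lower of 7567 genes, 1371 together (130 and 1368 without scaling factors), and 478, 697 and 692 without replicates 1, 2 and 3. The mean doublet score of cluster 17 was 0.0985, the highest of the tested classes, and its leading genes reached a log2 fold of 1.21 at most. Whether it holds doublets was not tested. Cluster 17 had higher ribosome biogenesis (4 of 42, 1 lower) and ribosomal protein lists (0 of 108 higher, 1 lower alone) and lower actomyosin and adhesion (8 of 39, 9 alone) and cell cycle lists (4 of 31), with CCNB1/CCNB2 at -1.37 ± 0.75. Oxidative phosphorylation (0 of 47) lost its call without replicate 1, 2 or 3, at 0.760, 0.231 and 0.158, and endoplasmic reticulum secretion (0 of 42) without replicate 1 or 2, at 0.193 and 0.105. It had 44 higher and 573 lower of 7581 genes, 617 together (70 and 521 with DESeq2's size factors), and 152, 293 and 298 without replicates 1, 2 and 3. In cluster 20 the signalling adaptor TRAF2/TRAF1 (c103678_g1) was at 4.72 ± 0.77 and the ubiquitin ligase RLIM at 2.70 ± 0.79, and its 1 called list, non-collagen matrix and integrins (1 of 22 higher, 1 lower), was lost without replicate 1 or 3, at 0.562 and 0.343. It had 153 higher and 95 lower of 7583 genes, 248 together, and 145, 152 and 142 without replicates 1, 2 and 3. In cluster 25 the heat shock protein HSPA6/HSPA1B was at 9.75 ± 0.54 and the protease inhibitor CSTA at 4.51 ± 0.79. Ribosome biogenesis (0 of 42) was called higher, and so were ribosomal proteins (0 of 108), not called without replicate 2 at 0.0799, and endoplasmic reticulum secretion (0 of 41), not called without replicate 1, 2 or 3, at 0.451, 0.800 and 0.685. These calls are relative to the other tested genes, as the median log2 fold change of all tested genes was -0.29. In fry these lists pointed lower and were not called. It had 62 higher and 171 lower of 7587 genes, 233 together (84 and 109 with DESeq2's size factors), and 105, 89 and 76 without replicates 1, 2 and 3. The 20 lists of these 4 clusters had adjusted p between 2.72e-14 and 0.0385, and between 0.819 and 0.833 with an estimated correlation.

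Over all 21 tested classes, 150 of 483 pairs of a list and a class were called, 94 higher and 56 lower, and 0 were called with an estimated correlation, where 17 had an unadjusted p under 0.05, and fry called 103. With an estimated correlation the lowest adjusted p was 0.819, and so few libraries could hardly give a call there. Presynaptic release was called higher in 9 classes and lower in 2, and postsynaptic scaffold higher in 6 and lower in 3. The presynaptic release list was drawn up for vesicle release at synapses in other animals, but not all its members are confined to that. It was written to take in general vesicle fusion genes such as NSF and the VAMP family. Symbols were matched by their start, so RAB26/RAB37 entered through RAB3. Actin motility was called higher in 9 and lower in 1, oxidative phosphorylation higher in 9 and lower in 3, and ribosomal proteins higher in 7 and lower in 7. All these calls are relative to the other tested genes, and some had no member past the gene threshold. Innate immunity was not called in any of the 21 classes in camera, with an unadjusted p under 0.05 in 4 and a lowest adjusted p of 0.0542. Channels and receptors were called lower in 3 classes and higher in 0. The median and the mean of a called list differed in sign in 15 cases, and against the direction of the test ran the median in 4 and the mean in 17. Over the 21 classes together, 11098 calls were higher and 21825 lower, 32923 in all, and 21414 without replicate 1. The excess of lower calls may depend on the filter, which the sums of all other cells can pass alone. Without replicate 1 a sum of the class had to pass it too in classes tested in 3 libraries. Cluster 14 then had 108 higher and 8 lower and cluster 19 353 and 398, while cluster 3 had 315 and 630.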

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

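The test on library 2's depth was chosen only after the cluster shares were seen, as were the comparisons that led to it. In 371 groups of 4 libraries, 1 library stood apart from the other 3 by its gap relative to the whole range in 48 of 357 gene groups, 40 times library 4 and 8 times library 2. Chance does so in about 1 in 20 groups if the 4 values have equal spread and the groups are independent. Neither holds here, as groups share cells and genes. Library 4 held the fewest cells, with 11 in cluster 9 and 17 in cluster 4, so counting noise alone can set it apart more often. Median UMIs per cell were 3820 in library 4. Its share of cluster 6 was 9.62% and of cluster 12 8.59%, each above the other 3 libraries. Among the genes named above, DUOX1 (c102802_g2) in cluster 4 stood at 3.78 in library 4 and the RAC2/RAC3 ID (c102226_g1) in cluster 4 at 2.69 in library 2. PI16 and SRF (c79489_g1) in cluster 9 stood at 4.27 and 2.02 in library 4.

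Cluster 5 held 93.7% (549 of 586) of the joined cluster 5 and archaeocyte-like cells of library 2, and 4.53%, 8.59% and 53.1% of those of libraries 1, 3 and 4, while at resolution 0.5 no class matched cluster 5 and the archaeocyte-like class took 28.4% of library 2. The lower depth of library 2 was argued against, since among joined cells of at least 20667 UMIs 92.6% (226 of 244, exact 95% interval 88.6 to 95.6) were in cluster 5 there, and 1 of 576 and 0 of 329 in libraries 1 and 3, but depth stays open for the few cluster 5 cells of libraries 1, 3 and 4, nearly all of lower depth. A library-wide difference may have split 1 type, as the ratios of library 2 to libraries 1 and 3 in the joined cells correlated with those in all other cells at Pearson r = 0.950 across 3452 held-out genes, which are not independent. The archaeocyte markers differed between these clusters but cannot decide whether they are 1 type. Cluster 5 had 0 of 12 at least 2-fold higher and a median log2 fold of -0.24, against 4 of 12 and 0.41 in cluster 1. Each cluster was there set against cells that included the other. Counts were pooled over libraries, so the folds of cluster 5, mostly of library 2, can also carry the library-wide difference. Within libraries, cluster 5 differed from the archaeocyte-like class at 1 of 5921 genes in edgeR. The joined cells took 23.7%, 25.6%, 25.2% and 11% of libraries 1 to 4. No biological explanation was tested, since the labels give 1 group.

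Cluster 11 took 23.4% (68 of 291) of library 4 and 2.26%, 2.49% and 2.29% of libraries 1 to 3. The lower UMI minimum of library 4 was argued against as the whole cause, since 12.04% (13 of 108, exact interval 6.57 to 19.7) of its cells at or above 4814 UMIs were in cluster 11, although this share is lower than 23.4%. For low depth moving other choanocyte-like cells there, 500 such cells of libraries 1 to 3 were thinned to 3277 UMIs. Each was assigned to the cluster profile it correlated with most, and 1.8% went to cluster 11, and 1.6% before thinning. This argues against low depth changing the closest profile. The profiles were summed from cells that included these, and the thinned cells were not clustered again. Whether low depth moved cells in the clustering itself was therefore not decided. A different make-up of the cells loaded in library 4 stays open, and no biological explanation was tested.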

How the results depend on the processing

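The comparisons within the choanocyte-like class and of cluster 5, and leaving out replicates 2 and 4 together, were chosen only after the results were seen. Of 657 gene and class pairs named by the rule, 601 kept their call in DESeq2, 650 with its size factors, 644 with no factors and 643 with no count filter, and the others lost it with the same direction. Of 183 called lists, 182, 173 and 181 kept it with DESeq2's size factors, no factors and no filter, and 96 in fry. The comparison with pinacocyte-like cells and its settings were not run, and the minimum of 500 genes per cell removed 0 cells and so tested nothing. For each count below the value reported follows in parentheses, and the cause was not tested except where fewer libraries or genes were used.

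DESeq2 gave 1355 for cluster 5 (2200), 324 for cluster 17 (617), 186 for cluster 23 (307), 120 for cluster 25 (233) and 0 for cluster 5 against archaeocyte-like (1). DESeq2's size factors gave 3 for cluster 5 against archaeocyte-like (1). With no scaling factors the counts were 3387 for cluster 14 (960) and 3 for cluster 5 against archaeocyte-like (1). A minimum of 50 UMIs, which tests fewer genes, gave 1883 for choanocyte-like against archaeocyte-like cells (2928), 1081 for clusters 11 and 15 against 7 and 8 (2002) and 0 for cluster 5 against archaeocyte-like (1). At Leiden resolution 0.5 the counts were 1967 for cluster 12 (839). At resolution 2.0 they were 2 for cluster 5 against archaeocyte-like (1). With doublets kept they were 6 for cluster 5 against archaeocyte-like (1). With all genes used to cluster they were 1253 for cluster 22 (571) and 25 for cluster 5 against archaeocyte-like (1). With the sets of genes swapped they were 1324 for cluster 12 (839), 385 for cluster 17 (617), 1373 for cluster 22 (571) and 15 for cluster 5 against archaeocyte-like (1). With no minimum fold, which is a looser threshold, they were 55604 for all 21 classes together (32923), 4926 for archaeocyte-like cells (2844), 5191 for choanocyte-like cells (3307), 3030 for cluster 2 (1202), 4024 for cluster 3 (1675), 5112 for cluster 4 (2987), 2711 for cluster 6 (1069), 4110 for cluster 9 (2659), 3385 for cluster 10 (2059), 1500 for cluster 12 (839), 3427 for cluster 16 (1371), 1692 for cluster 17 (617), 1473 for cluster 18 (764), 445 for cluster 20 (248), 862 for cluster 22 (571), 3189 for clusters 11 and 15 against 7 and 8 (2002), 11 for cluster 5 against archaeocyte-like (1) and 5525 for archaeocyte-like with cluster 5 (2997).

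Without the replicate block, which leaves 62 of the 657 named pairs and 10 of the 183 lists uncalled, the counts were 787 for cluster 2 (1202), 573 for cluster 6 (1069), 475 for cluster 12 (839), 294 for cluster 14 (960), 793 for cluster 16 (1371), 196 for cluster 17 (617), 306 for cluster 18 (764), 110 for cluster 20 (248), 814 for cluster 21 (1330), 335 for cluster 22 (571), 156 for cluster 23 (307), 79 for cluster 25 (233) and 0 for cluster 5 against archaeocyte-like (1). It moved no other count by over 1.5 times.

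Leaving out 1 replicate at a time gave 21414 to 32259 for all 21 classes together (32923), 945 to 1088 for cluster 3 (1675), 852 to 2044 for cluster 5 (2200), 1181 to 1431 for cluster 10 (2059), 492 to 934 for cluster 12 (839), 116 to 835 for cluster 14 (960), 478 to 697 for cluster 16 (1371), 152 to 298 for cluster 17 (617), 358 to 462 for cluster 18 (764), 751 to 1191 for cluster 19 (2361), 142 to 152 for cluster 20 (248), 363 to 790 for cluster 21 (1330), 235 to 405 for cluster 22 (571), 83 to 146 for cluster 23 (307), 76 to 105 for cluster 25 (233), 1309 to 1978 for clusters 11 and 15 against 7 and 8 (2002) and 0 to 6 for cluster 5 against archaeocyte-like (1). Leaving out replicates 2 and 4 together gave 20183 for all 21 classes together (32923), 784 for cluster 2 (1202), 1088 for cluster 3 (1675), 220 for cluster 5 (2200), 566 for cluster 6 (1069), 1362 for cluster 10 (2059), 502 for cluster 12 (839), 1853 for cluster 13 (3320), 697 for cluster 16 (1371), 293 for cluster 17 (617), 462 for cluster 18 (764), 1191 for cluster 19 (2361), 152 for cluster 20 (248), 790 for cluster 21 (1330), 83 for cluster 23 (307), 89 for cluster 25 (233) and 3 for cluster 5 against archaeocyte-like (1).

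Mean shares moved by over 1 SD to 10.8% for cluster 2 at resolution 2.0 (9.30%), 12.4% for cluster 3 at resolution 0.5 (6.74%), 5.51% for cluster 4 with all genes used to cluster (7.25%) and 3.5% for cluster 9 with doublets kept (4.67%). Within 1 SD, the share of cluster 12 was 2.53% without replicate 4 (4.05%) and that of cluster 5 was 3.03% without replicate 2 (8.26%). The archaeocyte-like share, with an SD of 11.3, stayed within it at 23.7% at resolution 0.5 and 19.4% with 1000 variable genes (13.1%). There it took 28.4% and 19.5% of library 2 (1.62%), and no class matched cluster 5. Clusters numbered 47 at resolution 2.0 in place of 31. With an estimated correlation camera called 0 of the 150 lists over all classes, of the 11 of choanocyte-like against archaeocyte-like cells, the 8 within choanocyte-like cells, the 1 of cluster 5 against the archaeocyte-like class and the 13 of the joined class, with an unadjusted p under 0.05 for 17, 1, 4, 0 and 1 lists. In fry these comparisons had 103, 21, 10, 0 and 17 lists. The estimated correlation rests on few residual degrees of freedom, so its 0 calls do not decide whether the lists differ.

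Directions turned in fry, which does not compare a list with other genes, with adjusted p of 0.522 for membrane transporters in cluster 13, 0.409 for actin motility in cluster 14, 0.215 for presynaptic release in cluster 19, 0.67 for transcription factors in cluster 19, 0.974 for non-collagen matrix and integrins in cluster 20, 0.13 for actin motility in cluster 21, 0.974 for actomyosin and adhesion in cluster 22, 0.451 for membrane transporters in cluster 22, 0.137 for actin motility in cluster 23, 0.479 for endoplasmic reticulum secretion in cluster 23, 0.451 for oxidative phosphorylation in cluster 23, 0.107 for presynaptic release in cluster 23, 0.24 for endoplasmic reticulum secretion in cluster 25, 0.498 for ribosomal proteins in cluster 25 and 0.265 for ribosome biogenesis in cluster 25. Without replicate 1 the direction of oxidative phosphorylation turned in clusters 17 and 23. Leaving out 1 replicate at a time gave adjusted p of 0.158 to 0.760 and of 0.311 to 0.959. ELMOD3 in cluster 13 went from -1.44 to 0.29 with the sets of genes swapped, AGRN in cluster 20 from 1.10 to -0.49 with all genes used to cluster and -0.0786 with the sets swapped, and TNXB (c103990_g2) in cluster 23 from -1.83 to 2.14 with doublets kept. The cause was not tested.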

Other observations

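The tests of the ratio of ribosomal protein IDs and all swaps of sums were chosen only after the results were seen. Several clusters too small for a test had leading genes of high fold, which were picked after their values were seen and are given as description. Cluster 28, with 27 cells, had dopamine beta-hydroxylase DBH at a log2 fold of 7.25 over all other cells and the homeobox gene MSX1 at 6.68, with TNXB (c103990_g2) at 6.50 and PI16 at 6.30, and 21 of 75 choanocyte markers at least 2-fold higher. Cluster 26, with 49 cells, had MLT-7 (c104361_g2), annotated as a peroxidasin, at 7.64 and a KCNMA1/KCNU1 ID, of the calcium-activated potassium channels, at 5.04. Cluster 27, with 33 cells, had an ITGAV/ITGA2B integrin ID (c102745_g1) at 5.87 and high CNN3 (c79401_g1). Cluster 30, with 25 cells, had the collagen COL11A2 at 7.27, and cluster 29, with 26 cells, a CSTA/CSTB ID, a cystatin, at 9.52. Clusters 24 and 31, with 58 and 18 cells, had mean doublet scores of 0.2175 and 0.1981.

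Of the ribosomal protein IDs, 40 were of low abundance next to 37 abundant IDs of the same proteins, and in choanocyte-like cells the median log2 fold change, with 39 of the 40 tested, was -0.08 ± 0.30 against -1.90 ± 0.17, and the low-abundance IDs together took 637, 310, 1031 and 205 CPM in libraries 1 to 4. Shared reads with the abundant IDs were argued against as the whole cause by the ratio of both medians, 0.04, but stay open for a part. Both rose in archaeocyte-like cells (0.31 against 1.27) and clusters 5 (0.33 against 0.90), 16 (0.185 against 0.69) and 21 (0.35 against 0.44). They did not both rise in clusters 17 (0.00 against 0.48), 14 (0.96 against -1.29), 4 (0.17 against -1.37) and 10 (0.18 against -1.21). The rise of the low-abundance IDs is close in size to what scaling added, so it is no evidence for shared reads. Without scaling factors the median of all genes moved by -0.29, -0.20, -0.18 and -0.28 in archaeocyte-like cells and clusters 5, 16 and 21. In cluster 14 it moved by -1.01. In unscaled counts the low-abundance IDs took 351 to 774 CPM over the tested classes, and the abundant IDs 14531 to 179040. A constant amount of free RNA per droplet was argued against by the slope of their UMIs on a cell's total UMIs on log scales, at the lowest 0.978 in libraries 1 to 3. Whether part of the cells carried this RNA could not be decided, as the variance over counting noise was at most 1.291 in libraries 1 to 3, and what set the levels apart between libraries was not tested. No biological explanation was tested.

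In each comparison the 2 sums of a library were also swapped in every other way, which gives 8 swaps with 4 libraries and 4 swaps with 3, too few for a share under 0.05. In 24 of the 25 comparisons 1 arrangement, the real one, gave as many genes. The classes were clusters of these same cells, set apart by their expression. A swap turns the contrast around in some libraries, so fewer calls follow from how the classes were made. These counts are therefore no evidence that a class differs. The real count and the highest other were 1069 and 478 in cluster 6, 2659 and 196 in cluster 9, 1202 and 148 in cluster 2, 3320 and 131 in cluster 13, 571 and 69 in cluster 22, 839 and 51 in cluster 12, 233 and 25 in cluster 25, 307 and 16 in cluster 23, 960 and 13 in cluster 14, 248 and 12 in cluster 20, and 764 and 1 in cluster 18. The highest other was 0 in the edgeR test of 13 comparisons, whose real counts were 2844, 3307, 1675, 2987, 2200, 2059, 1371, 617, 2361 and 1330 for the archaeocyte-like and choanocyte-like classes and clusters 3, 4, 5, 10, 16, 17, 19 and 21, and 2928, 2002 and 2997 for the direct, the within-choanocyte and the joined comparison. For cluster 5 against the archaeocyte-like class, 4 of 8 gave as many as the real 1, and the highest other was 6.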
